A study of Mus musculus with 6 samples.

How the data were processed

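Single-nucleus RNA was sequenced from lateral amygdala by droplet capture. Per the labels, the submitters' processing notes name Cell Ranger (no version given) on mm10 and Seurat 3. The authors deposited raw UMI counts per gene and barcode, over all 6794880 barcodes, without filtering by cell. Whether intron reads were counted is not given in the sources used here. The features were 32285 Ensembl genes and 1 added feature called mWake, whose sequence is not given in the sources used here, and 32235 of the 32286 identifiers matched the GENCODE annotation of mm10 from which coordinates were taken. Samples were grouped as cells or nuclei from their labels. Of 6 samples, 1 entered the analysis and 5 were not analysed here.

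Nuclei were barcodes with at least 1000 UMIs, at least 500 genes and at most 5% mitochondrial UMIs. Of 4633 barcodes with at least 1000 UMIs, 1261 exceeded the mitochondrial limit. Scrublet, run in scanpy 1.11.5, set its automatic threshold at 0.49 and marked 0 of 3372 nuclei, so it had not worked. A score threshold of 0.2 was then chosen after the scores had been seen and removed 104 nuclei (3.08%), leaving 3268. The lowest depth was 1002 UMIs and the highest 98126.

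Counts were scaled to 10000 per nucleus, log transformed and clustered (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 with python-igraph 0.11.9), with the genes of the lists, Ankfn1 and mWake kept out of the variable genes. The 24 clusters were named from markers fixed before the data were examined. The class with the most markers on was taken, a marker being on at 25% or more of the highest cluster's CPM with at least 10 CPM and 3 UMIs, and at least 3 markers and 50% of a class had to be on. Clusters stayed unnamed where 5 of the top 10 genes were mitochondrial or ribosomal (3 clusters, 417 nuclei), where a top gene marked another lineage (2 clusters, 65 nuclei) or where 5 of the top 10 genes were shared with a shallower cluster of another lineage (1 cluster, 42 nuclei). The doublet threshold, these cut-offs and the rules for unnamed clusters were set after clusters had been seen, with Ankfn1 and mWake levels per class visible. A filter on nuclei that carry markers of 2 lineages was also tried in 2 versions during that work. It was not part of the design, so it is left out of the results and given as an alternative. Doublets under the score threshold were not removed.

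CPM was computed from UMIs summed over the nuclei of a group. Sums carry exact Poisson intervals, shares Clopper-Pearson intervals and ratios the exact conditional binomial interval, all at 95% and for counting error only. A count of 0 allows up to 3 counts. Shares of nuclei with a UMI were taken after drawing each nucleus down to 1000 UMIs without replacement. Glia were the astrocyte-like, oligodendrocyte-like, oligodendrocyte precursor-like and microglia-like nuclei. Ankfn1-detected nuclei were glutamatergic neuron-like nuclei with an Ankfn1 UMI after thinning to 2000 UMIs. Genes with at least 100 UMIs over both groups and a UMI in at least 5% of either group were compared, leaving out Ankfn1, the mWake feature and mitochondrial genes. The genes named are Ankfn1, clock genes, the 12 highest and 12 lowest by the interval bound nearest to 1, and list members at least 25% higher or at most 0.8 by that bound. List members were counted only for lists fixed before the data were examined, and no count over all genes was made, since nuclei are not replicates. The comparison was tested on simulated counts with 200 changed genes: of 44 genes lowered 2-fold 61.4% passed the bound, of 47 lowered 1.5-fold 23.4%, and of 4555 unchanged genes 1.

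Alternatives fixed beforehand changed the depth and mitochondrial limits, doublets, resolution, principal components, thinning, free RNA, the unit and the weighting of undetected nuclei. Those added after seeing the data were a doublet threshold of 0.15, the filter on markers of 2 lineages, the naming of clusters left unnamed, the ratio between intercalated neuron-like sub-clusters under other settings, a free RNA share measured per class and a free RNA profile from barcodes of 200 to 500 UMIs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0 were used.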

Results

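The study profiled the lateral amygdala of male mice that carry Cre at 1 copy of the mWake locus, aged 7 to 8 weeks and sampled in the first hours of the light phase, zeitgeber hours 0 to 2. The series holds 6 samples in 2 groups, 3 of dissociated cells and 3 of isolated nuclei. Per the series design, both amygdalae of 2 mice entered a run. The results below come from nuclei replicate 4, the 1 sample for which a count matrix was used, and the other 5 samples were not analysed here. With 1 library there is no replicate check and no test between samples. All intervals are 95% intervals that cover counting error only, and nuclei are not replicates. The library held 62346524 UMIs (unique molecular identifiers, counts of captured RNA molecules). After filtering, 3268 nuclei remained, with a median of 12037 UMIs per nucleus, and they held 72.0% of all UMIs.

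Neurons made up most of the nuclei. Glutamatergic neuron-like nuclei numbered 1525, or 46.7% (Clopper-Pearson interval 44.9 to 48.4). GABAergic neuron-like nuclei numbered 561, or 17.2% (15.9 to 18.5), and of these 296 were intercalated neuron-like, 181 interneuron-like and 84 medium spiny neuron-like. Intercalated neurons are clusters of inhibitory cells that border the lateral and basal amygdala. The glial classes together held 624 nuclei, with 323 astrocyte-like, 112 microglia-like, 100 oligodendrocyte precursor-like and 89 oligodendrocyte-like nuclei, and 20 endothelial-like and 14 ependymal-like nuclei completed the named set. The labels give mWake-expressing neurons as the cell type, and these glial nuclei lie outside that description. A further 524 nuclei (16.0%) stayed unnamed. Of these, 417 fell in clusters led by mitochondrial or ribosomal genes, and naming those clusters by their markers, a setting chosen after seeing the data, raised the glutamatergic share to 55.4%. Glial nuclei were shallower (median 3747.5 UMIs) than neurons (median 15555.5 UMIs).

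The study centres on mWake, known from background knowledge as the gene Ankfn1 (ENSMUSG00000047773), which lies on chromosome 11 from 89390223 to 89777653 on the minus strand of mm10 and is annotated as protein coding. The first comparison asked which classes carry its RNA. All nuclei came from mice that carry Cre at 1 copy of this locus, so whether Cre alters Ankfn1 RNA could not be tested here. Ankfn1 was highest among neurons in intercalated neuron-like nuclei, at 364 CPM (UMIs of the gene scaled to 1000000 summed UMIs, Poisson interval 343 to 386). It reached 139.7 CPM (135 to 144) in glutamatergic neuron-like nuclei, 56.0 CPM (48.3 to 64.6) in interneuron-like and 26.2 CPM (18.3 to 36.5) in medium spiny neuron-like nuclei. The intercalated level was 2.61-fold the glutamatergic level (2.44 to 2.79) and 6.50-fold the interneuron level (5.57 to 7.63). Neurons together stood 4.96-fold above glia (3.96 to 6.30). Among glia, oligodendrocyte precursor-like nuclei carried 98.9 CPM (76.0 to 126.6), against 4.50 CPM (1.65 to 9.79) in astrocyte-like and 8.87 CPM (1.83 to 25.9) in oligodendrocyte-like nuclei. The highest level of any class was that of the 14 ependymal-like nuclei, 591 CPM (469 to 734) from 81 UMIs. These nuclei also carried some neuronal and intercalated markers above the level of all glia, with Foxp2 at 314 against 14.2 CPM, Meis2 at 948 against 337 CPM and Syt1 at 890 against 264 CPM. Gad1 (7.29 against 18.4 CPM, from 1 UMI) and Slc17a7 (36.5 against 47.2 CPM, from 5 UMIs) were lower. Foxp2 and Meis2 lay below their intercalated neuron-like levels of 1876 and 2274 CPM, while Ankfn1 lay above its intercalated level. That intercalated level pools sub-clusters described below. The highest of them, at 639 CPM (600 to 680), overlapped the ependymal-like interval. No Ankfn1 UMI was counted in the 20 endothelial-like nuclei, which allows up to 28.3 CPM.

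**Figure D1:**
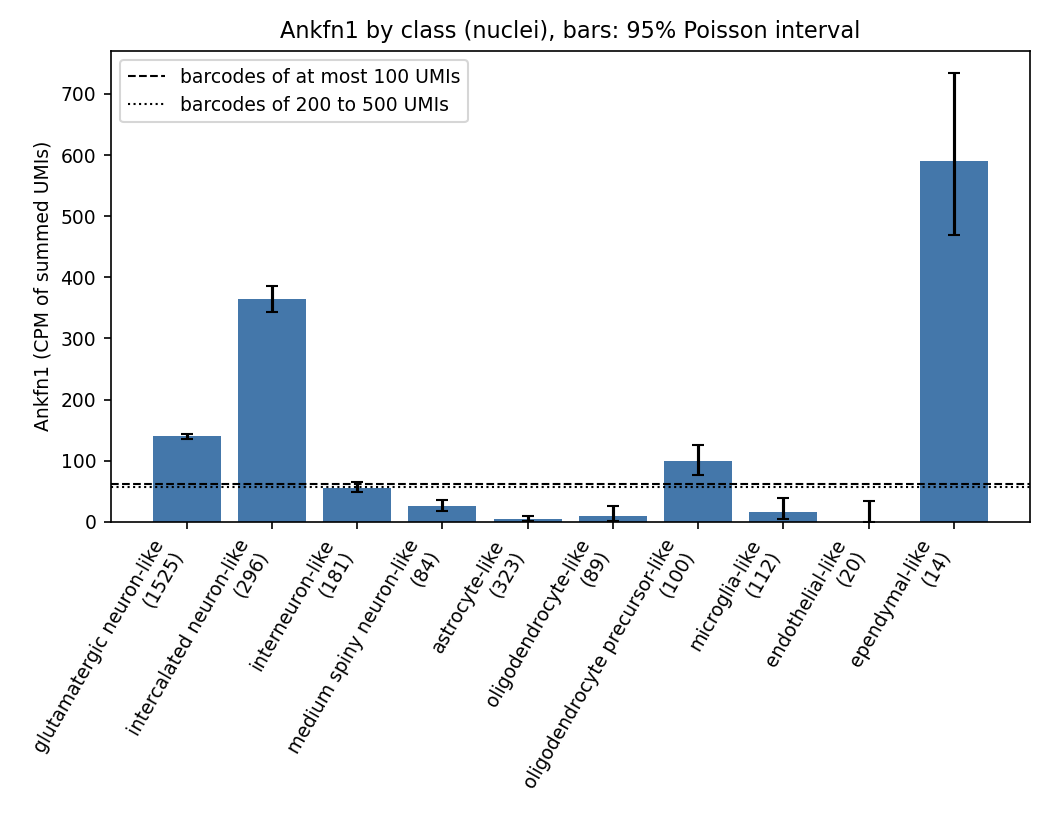
Ankfn1 in CPM of summed UMIs (vertical axis) for each named class (horizontal axis, number of nuclei in brackets), with 95% Poisson intervals as error bars and the levels in 2 sets of low-count barcodes as lines. Intercalated neuron-like nuclei reach 364 CPM and glutamatergic neuron-like nuclei 139.7 CPM, while ependymal-like nuclei, few in number, stand highest at 591 CPM.

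Detection followed the same order once each nucleus was thinned to 1000 UMIs. An Ankfn1 UMI was then present in 29.4% of intercalated neuron-like nuclei (24.3 to 34.9), 13.0% of glutamatergic neuron-like nuclei (11.4 to 14.8), 5.52% of interneuron-like nuclei (2.68 to 9.93) and 0.31% of astrocyte-like nuclei (0.0078 to 1.71), the class used as background. No nucleus of these classes was left out by the thinning. Without thinning, the glutamatergic share was 73.97% and the intercalated share 61.49%, in the reverse order, with median depths of 16909 and 8228.5 UMIs. The median depth of astrocyte-like nuclei was 3869 UMIs, and 1.86% of them held an Ankfn1 UMI without thinning. Barcodes of at most 100 UMIs, taken as free RNA, held 62.2 CPM of Ankfn1 (53.2 to 72.4). The levels of interneuron-like nuclei overlapped that value, and those of medium spiny neuron-like nuclei lay below it. That value is the level in free RNA alone. The free RNA share of neurons, measured with oligodendrocyte and microglia markers after seeing the data, was 19.5%. A level at or below that value thus does not show that free RNA supplied these UMIs.

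Within neurons, re-clustered alone into 15 sub-clusters, Ankfn1 was concentrated in a few. Sub-cluster 6, which held 185 nuclei of which 99.5% were intercalated neuron-like, carried 639 CPM (600 to 680), and 43.8% of its thinned nuclei had an Ankfn1 UMI (36.5 to 51.3). The other intercalated neuron-like sub-cluster was number 10, with 95 nuclei. Drd1, a marker used for that name, lay there below the 10 CPM that an on marker needs. Sub-cluster 10 carried 33.4 CPM of Ankfn1 (22.2 to 48.3), a 19.1-fold difference (13.1 to 28.9) from sub-cluster 6. The size of this difference depended on the clusters: it was 8.38-fold at resolution 0.5, 8.36-fold with a cluster of 42 unnamed nuclei kept in its class and 9.52-fold with mitochondrial and ribosomal clusters named, all read after seeing the data, while the highest sub-cluster stayed between 637 and 648 CPM in these 3. Among glutamatergic neuron-like sub-clusters, number 12 (74 nuclei) reached 274 CPM (248 to 303) and number 1 (297 nuclei) 266 CPM (253 to 281). The remaining glutamatergic sub-clusters lay between 83.4 and 144 CPM. The median over all 15 sub-clusters was 91.0 CPM, and sub-cluster 6 stood 7.02-fold above it.

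**Figure D2:**
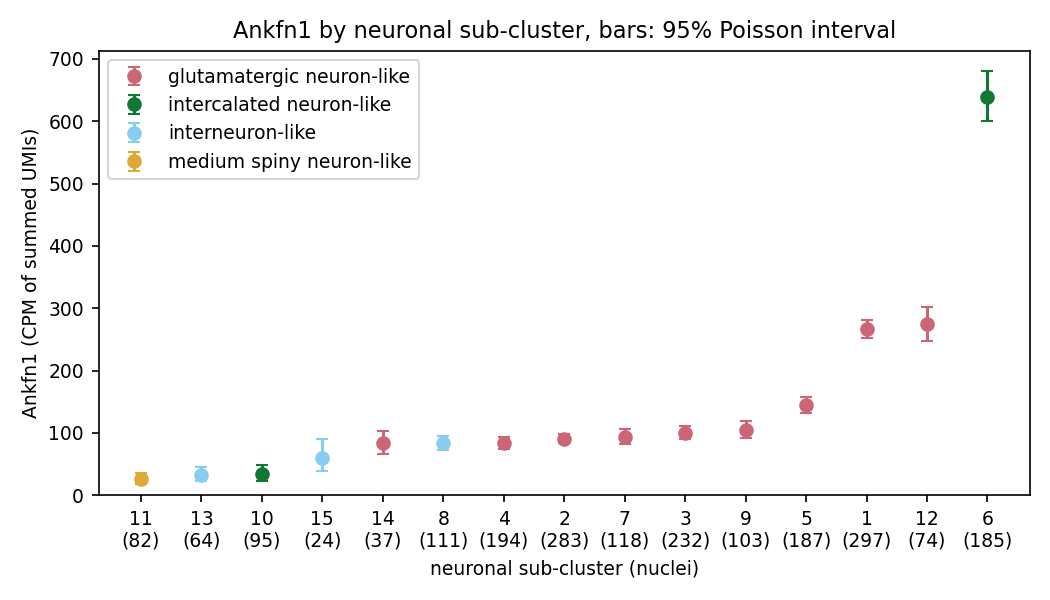
Ankfn1 in CPM of summed UMIs (vertical axis) in the 15 neuronal sub-clusters, ordered by level (horizontal axis, number of nuclei in brackets), coloured by the class of most of their nuclei, with 95% Poisson intervals. Sub-cluster 6 stands at 639 CPM and the other intercalated neuron-like sub-cluster, number 10, at 33.4 CPM.

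The series title names a local oscillator of the amygdala, so the 23 clock genes of the list were compared between classes. Between glutamatergic and GABAergic neuron-like nuclei, of 23 members, 1 was higher and 3 were lower in glutamatergic nuclei, meaning that the interval bound nearest to 1 was at least 25% higher or at most 0.8. Rorb (ENSMUSG00000036192, protein coding, chromosome 19 from 18930605 to 19111196), a nuclear receptor of the ROR family, was the higher one, at 131.9 against 36.4 CPM (ratio 3.62, 3.20 to 4.10). Per1 (ENSMUSG00000020893, protein coding, chromosome 11 from 69095217 to 69109960), a period gene and repressor of the clock loop, stood at 16.7 against 25.9 CPM (ratio 0.64, 0.55 to 0.76). Bhlhe41, also a repressor of that loop and among the lower ones, stood at 13.0 against 26.0 CPM (ratio 0.50, 0.42 to 0.60). The GABAergic classes differed among themselves. Against glutamatergic nuclei, intercalated neuron-like nuclei had 8 members higher and 1 lower by that bound, medium spiny neuron-like nuclei 4 higher and 2 lower, and interneuron-like nuclei 1 higher and 6 lower. Per1, Nr1d2, Dbp, Tef, Hlf, Bhlhe40 and Bhlhe41, all higher in intercalated neuron-like nuclei, also stood higher in barcodes of 200 to 500 UMIs than in nuclei (1.27 times for Nr1d2 to 5.08 times for Dbp). Per3, the other higher member, stood lower there (0.48 times, 0.40 to 0.56). The free RNA share by oligodendrocyte and microglia markers was 18.1% in intercalated and 18.8% in glutamatergic neuron-like nuclei, measured after seeing the data. With these shares subtracted, Per1, Per3, Nr1d2, Tef, Hlf, Bhlhe40 and Bhlhe41 stayed higher by that bound. Their ratios ran from 1.66 for Per3 (1.46 to 1.90) to 4.31 for Bhlhe41 (3.30 to 5.60). The subtraction left no Dbp in glutamatergic neuron-like nuclei, so the shares are too large for some genes and these ratios are uncertain. Per1 stood at 36.8 CPM in intercalated neuron-like nuclei (2.21 times the glutamatergic level, 1.78 to 2.72) and 16.1 CPM in interneuron-like nuclei (0.97 times, 0.71 to 1.28). Bhlhe41 stood at 34.2 CPM in intercalated neuron-like nuclei (2.63 times, 2.09 to 3.27), 39.7 CPM in medium spiny neuron-like nuclei (3.05 times, 2.24 to 4.08) and 13.1 CPM in interneuron-like nuclei (1.01 times, 0.72 to 1.38). In glutamatergic against all GABAergic nuclei, the activators Clock and Arntl had ratios of 0.95 (0.88 to 1.03) and 1.08 (0.98 to 1.19). The Rorb ratio was 6.35 as a mean over nuclei, and 7.47 when the doublet score threshold was lowered to 0.15, a setting chosen after seeing the data.

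Against glia, neurons had lower CPM of many clock genes, with 11 of 23 members lower and 0 higher by the same bound. CPM is a share of the UMIs of a class and not an amount per nucleus, and median depth was 15555.5 UMIs in neurons and 3747.5 in glia. No share over all genes was taken, so whether this difference is particular to clock genes was not tested. Rorb stood at 111.5 CPM in neurons and 725 CPM in glia (ratio 0.15, 0.15 to 0.16), Rora at 943 against 2272 CPM (0.42, 0.40 to 0.43), Per1 at 18.6 against 78.3 CPM (0.24, 0.20 to 0.28) and Bhlhe40 at 7.49 against 29.6 CPM (0.25, 0.20 to 0.33). Clock itself did not differ detectably from all glia together (ratio 1.04, 0.92 to 1.18), but the glial classes went opposite ways. Neurons stood at 1.29 times astrocyte-like (1.07 to 1.57) and 1.63 times microglia-like nuclei (1.06 to 2.68). They stood at 0.73 times oligodendrocyte-like (0.56 to 0.99) and 0.77 times oligodendrocyte precursor-like nuclei (0.63 to 0.96). None of these Clock ratios passed the bound. The lower levels of clock genes in neurons lay mostly against astrocyte-like nuclei, where 15 of 23 clock genes were higher than in neurons by that bound and 0 lower. Against neurons, microglia-like nuclei had 4 members higher and 5 lower, oligodendrocyte precursor-like nuclei 2 higher and 2 lower, and oligodendrocyte-like nuclei 1 higher and 3 lower. Rorb and Rora went the other way in 2 classes. Neurons stood above oligodendrocyte-like nuclei (Rorb 4.72 times, 2.39 to 10.9, and Rora 7.98 times, 5.86 to 11.2). They also stood above microglia-like nuclei (Rorb 6.60 times, 2.83 to 20.3, and Rora 8.46 times, 6.02 to 12.3). Per1 in neurons also lay below its level in barcodes of at most 100 UMIs, 25.2 CPM (19.6 to 31.9). All samples were taken in 1 window of the day, so these are levels and not rhythms.

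**Figure D3:**
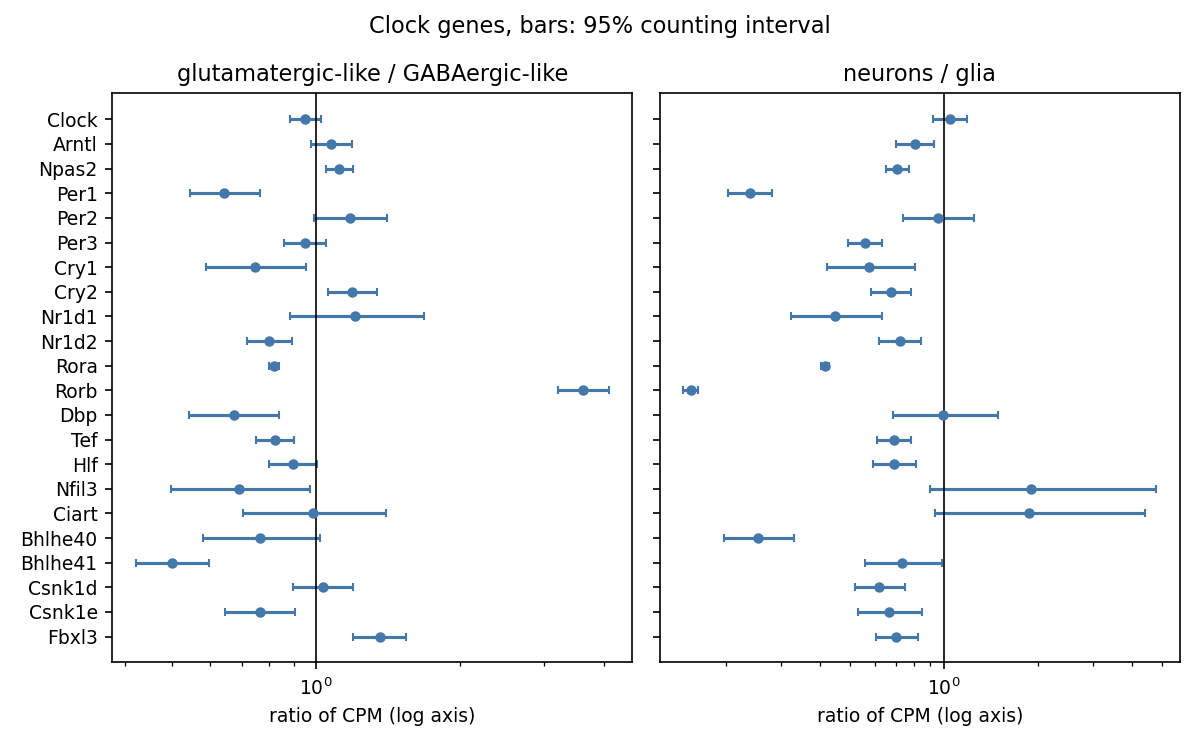
Ratio of CPM (horizontal, log axis) for clock genes of the list, for glutamatergic against GABAergic neuron-like nuclei on the left and neurons against glia on the right, with 95% counting intervals. Rorb lies at 3.62 on the left and 0.15 on the right, and Clock lies near 1 in both.

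The last comparison asked what distinguishes glutamatergic neuron-like nuclei in which Ankfn1 was detected. After thinning to 2000 UMIs, with 13 shallower nuclei left out, 342 nuclei held an Ankfn1 UMI and 1170 did not. Without thinning, 1128 held an Ankfn1 UMI and 397 did not. Most nuclei called undetected thus held Ankfn1 UMIs that the thinning removed, and they are not nuclei without Ankfn1. The genes with the highest ratios by the rule were Rorb (ratio 2.36, 1.93 to 2.87), Kcnk2, a potassium leak channel (2.57, 1.73 to 3.79), Lhfp (2.54, 1.67 to 3.83), Erbb4, a neuregulin receptor (1.97, 1.64 to 2.36), Frem1 (1.92, 1.42 to 2.57), Clvs2 (1.96, 1.41 to 2.69), Boc (1.88, 1.41 to 2.49), Tafa2 (1.52, 1.37 to 1.69), Rbpj, the transcription factor of Notch signalling (1.85, 1.33 to 2.54), H13 (1.83, 1.32 to 2.50), Bmpr1b, a BMP receptor (1.74, 1.32 to 2.28), and Sorcs1 (1.46, 1.30 to 1.64). The lowest were the long noncoding RNA 6530403H02Rik (0.54, 0.44 to 0.66), Stxbp6 (0.43, 0.27 to 0.67), Otof (0.45, 0.27 to 0.70), Col23a1 (0.44, 0.26 to 0.71), Sgk3 (0.38, 0.17 to 0.72), Gm32647 (0.63, 0.53 to 0.74), Adcy10 (0.44, 0.24 to 0.75), Slc24a2 (0.57, 0.43 to 0.75), Arhgap26 (0.62, 0.50 to 0.76), Rfx3 (0.68, 0.59 to 0.77), Cdh13, a cadherin (0.70, 0.63 to 0.77), and Prtg (0.53, 0.36 to 0.78). The share of nuclei with Ankfn1 detected differed between sub-clusters, with 39.2% in number 1 and 40.8% in number 12 against 12.5% in number 4, 13.7% in number 9 and 15.5% in number 2, and 0 of 3 nuclei in number 8. Rorb, Lhfp and Bmpr1b are among the 10 top genes of sub-cluster 1, and Rfx3, Gm32647, Col23a1 and 6530403H02Rik among those of sub-cluster 2. These genes were selected for their extreme ratios: with thinning to 4000 UMIs Clvs2 stood at 1.04, H13 at 1.06, Rbpj at 1.19, Sgk3 at 0.74, Prtg at 0.84 and Adcy10 at 0.95, and without thinning H13 at 0.994, Boc at 1.19, Otof at 0.84 and Lhfp at 4.09. With undetected nuclei weighted to the sub-cluster mix of the detected ones, the ratios were 1.34 for Rorb (1.09 to 1.65), 1.52 for Kcnk2 (1.01 to 2.28), 1.40 for Lhfp (0.91 to 2.15), 1.02 for Sorcs1 (0.90 to 1.15) and 0.94 for Rfx3 (0.82 to 1.08), while Clvs2 stood at 2.08 (1.47 to 2.95), H13 at 1.92 (1.36 to 2.69) and Rbpj at 1.76 (1.24 to 2.48). With weighting, most of the named higher genes stayed above 1 by their interval, and most of the lower genes stayed below 1. Among the lower genes were Sgk3 at 0.46 (0.21 to 0.91), Otof at 0.51 (0.31 to 0.80), Prtg at 0.58 (0.38 to 0.85) and Arhgap26 at 0.68 (0.55 to 0.84).

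Few members of the fixed gene lists passed the bound in this comparison, and how many did depended on the settings. Over all lists 1 was higher and 0 lower, against 0 and 0 with weighting to the sub-cluster mix, 2 and 3 with thinning to 4000 UMIs, and 6 and 8 without thinning. Of the 23 clock genes, 12 were measured, with 1 higher by that bound (Rorb) and 0 lower, and the list's median log2 ratio of 0.13 lay at percentile 96.1 among 10000 random lists matched on expression, and with weighting to the sub-cluster mix the median was 0.07 at percentile 84.5. The list of neighbouring cortex and claustrum genes, with 3 of 8 measured, also had 1 higher, again Rorb, and a median of 0.21 at percentile 96.5 (96.8 with weighting). No member passed that bound in the other lists. Their medians lay at percentile 52.0 for 23 excitability channels (51.9 with weighting), 34.9 for 25 GABA and glutamate receptors (14.2), 75.1 for 9 modulator receptors (40.2), 22.1 for 2 neuropeptides (5.4) and 20.3 for 3 basolateral complex genes (43.2). No immediate early gene had enough UMIs. In simulated counts of this size, 90.0% of 50 genes raised 2-fold passed the bound, but 28.6% of 49 genes raised 1.5-fold, so smaller differences were often not detectable at this depth.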

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

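Signals outside the comparisons of the report are given here. The tests on the mWake feature, and those of free RNA and depth for Ankfn1, were chosen only after the results were seen.

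The feature called mWake, counted apart from Ankfn1, had 262 UMIs in the called nuclei, above the 3 that a count of 0 allows. In barcodes of 200 to 500 UMIs it stood at 47.1 CPM (41.5 to 53.2), against 5.84 CPM in nuclei. Unnamed nuclei held 73 of its UMIs, at 12.8 CPM (10.0 to 16.1), against 4.63 CPM in neurons. In neurons, its UMIs were 0.50 times what a free RNA share measured with oligodendrocyte and microglia markers predicts (0.43 to 0.59). Free RNA could thus account for them, but any count up to the prediction passes this test. It cannot decide between free RNA and RNA held inside the nuclei. The count lies below the prediction by more than its interval, so the free RNA share of 19.5% overstates this feature in neurons. RNA held inside the nuclei that follows Ankfn1 is argued against as the whole source of these UMIs. The mWake ratio of neurons to glia was 0.75 (0.45 to 1.35), beside 4.96 for Ankfn1. If the UMIs are free RNA, this ratio cannot tell which cells make it. Whether a part follows Ankfn1 within neurons stays open, with 10 UMIs in sub-cluster 6. What sequence the feature holds is not known here, and no biological explanation was tested.

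Barcodes of at most 100 UMIs held Ttr, a choroid plexus gene, at 1010 CPM, while barcodes of 200 to 500 UMIs held 0.74 CPM and the called nuclei 6 UMIs. The planned free RNA profile thus differs from that of barcodes of 200 to 500 UMIs.

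The high Ankfn1 level of intercalated neuron-like sub-cluster 6 was set against 3 technical explanations. Free RNA is argued against, since the sub-cluster's Ankfn1 CPM was 11.1 times that of barcodes of 200 to 500 UMIs (9.73 to 12.6). Depth is argued against, since between nuclei within the same range of depth, 6078 to 10218 UMIs, the ratio to glutamatergic neuron-like nuclei was 4.43 (3.75 to 5.24). Reads of a neighbouring gene stay open: the flanking genes on the same strand, Nog and Pctp, had a ratio of 3.24 (1.11 to 7.81) from 6 UMIs in the sub-cluster, too few to decide, beside 994 Ankfn1 UMIs there, and no annotated gene overlaps Ankfn1. No biological explanation was tested.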

How the results depend on the processing

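Settings chosen only after seeing the data are the doublet threshold of 0.15, the filter on markers of 2 lineages, the naming of unnamed clusters, the free RNA profile of 200 to 500 UMIs, the free RNA share per class and each change to the ratio between intercalated neuron-like sub-clusters. The glutamatergic neuron-like share was 36.24% with 500 UMIs and 300 genes, 52.12% with 2000 UMIs and 1000 genes, 49.72% with at most 1% mitochondrial UMIs, 44.69% with doublets kept, 49.14% with 15 principal components and 55.39% with mitochondrial and ribosomal clusters named. The GABAergic neuron-like share was 12.39% with 500 UMIs, 18.74% with 2000 UMIs and 14.6% at resolution 0.5. Ankfn1 in intercalated neuron-like nuclei was 414.3 CPM with 500 UMIs, 411 CPM with the 0.15 threshold, 394.6 and 396.3 CPM with free RNA of at most 100 and of 200 to 500 UMIs subtracted, and 401.7 CPM as a mean per nucleus. In glutamatergic neuron-like nuclei the 2 subtractions gave 146.4 and 147.2 CPM. The intercalated to glutamatergic ratio was 3.0 with 500 UMIs, 2.903 with the 0.15 threshold and 2.873 as a mean per nucleus, and it stayed above 1 in each setting run. Shares of nuclei with an Ankfn1 UMI without thinning were 73.97% (glutamatergic) and 61.49% (intercalated). The ratio of the highest to the lowest intercalated neuron-like sub-cluster was 8.377 at resolution 0.5, 8.362 with the cluster led by another lineage's genes kept and 9.518 with mitochondrial and ribosomal clusters named. At resolution 0.5, 2 clock genes were higher in glutamatergic than in GABAergic neuron-like nuclei. In Ankfn1-detected nuclei, list members higher by the bound numbered 2 with thinning to 4000 UMIs, 6 without thinning and 0 with weighting. Those lower numbered 1 with thinning to 1000 UMIs, 3 with 4000 and 8 without. The H13 ratio was 0.9941 without thinning. The cause of these changes was not tested. Both versions of the filter on markers of 2 lineages left each class result within its interval or 1.5 times its count. Leaving out a sub-cluster that mixes transmitters was not run, as none met its limit. No paired analysis was possible because 1 library was used.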

Other observations

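The tests of the sub-cluster mix and of gene length were fixed before their results were seen, but the requirement that an interval clear the limit was applied to the mix after its value of 0.51 had been seen, and without it that value would have argued against the mix. The groups described in the next 2 paragraphs were picked after their levels had been seen.

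The 2 intercalated neuron-like sub-clusters differed in many list genes besides Ankfn1. Sub-cluster 6 had higher Penk, which encodes enkephalin (410 against 49.0 CPM, ratio 8.38, 6.10 to 11.8), higher Tac1, the substance P precursor (119 against 3.58 CPM, ratio 33.2, 11.2 to 162), higher Drd1, a dopamine receptor (81.0 against 5.97 CPM, ratio 13.6, 5.66 to 42.5), and higher Adra1a (ratio 24.0, 8.05 to 118). Sub-cluster 10 had higher Chrm2, a muscarinic receptor (270 against 14.1 CPM, ratio 0.052, 0.032 to 0.081), and higher Gria3, an AMPA receptor subunit (707 against 100.3 CPM, ratio 0.14, 0.12 to 0.17). By the interval bound nearest to 1 (at least 25% higher, or at most 0.8), 5 of 29 GABA and glutamate receptors were higher and 11 lower in sub-cluster 6, and of 26 excitability channels 5 were higher and 4 lower, with Kcnq5 at 6.61-fold (5.61 to 7.84). Of 23 clock genes 1 was higher, Npas2, at 235 against 53.7 CPM (ratio 4.38, 3.21 to 6.11). Which nuclei form sub-cluster 10 varied with the settings, and these lists were read for the main clusters only. Penk is also among the 10 genes that set sub-cluster 6 apart from other neurons, and Drd1 is among the markers used for names. In sub-cluster 10 Drd1 lay below the 10 CPM that an on marker needs. Whether the 2 sub-clusters are the same cell type was not tested.

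Glutamatergic neuron-like sub-cluster 9, with 102 such nuclei, was picked for the highest mean of the immediate early genes among the glutamatergic sub-clusters. Neurons induce these genes within minutes of activity. Bdnf stood at 166 CPM there against 6.20 CPM in the other glutamatergic neuron-like nuclei (ratio 26.7, 22.2 to 32.4), Nr4a3 at 99.7 against 7.98 CPM (12.5, 10.3 to 15.2) and Fos at 22.4 against 1.89 CPM (11.8, 7.79 to 17.9). Of 23 clock genes 1 was higher by the bound above, Per1 (ratio 1.85, 1.39 to 2.41), and 1 lower, Hlf (ratio 0.52, 0.39 to 0.69), and Ankfn1 was 0.73 times the level of the others (0.63 to 0.83).

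The genes higher in Ankfn1-detected glutamatergic neuron-like nuclei were set against 2 explanations. A shift shared by genes of like length is argued against as the whole cause: over all compared genes the medians of the length groups ran only from -0.04 to 0.03. With them subtracted the median log2 ratio of the 12 named higher genes went from 0.92 to 0.93 (0.77 to 1.09). This test cannot see a wider spread of ratios among long genes, so that form of gene length stays open. Most named genes, higher and lower, were longer than the median compared gene, 64.8 kb. The mix of sub-clusters cannot be told apart from a difference within them: with undetected nuclei weighted to the mix the median was 0.51 (0.35 to 0.67), and the value that would have argued against the mix, 0.46, lies inside that interval. The 12 genes were picked for high ratios on the same nuclei, which raises their median before and after either correction. No biological explanation was tested.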
